A study of Mus musculus with 15 samples.

How the data were processed

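RNA was measured in 15 libraries of mouse neural progenitor cells, which are dividing precursors of neurons and glia, in 5 groups of 3 libraries. Per the labels, the cells were kept with the growth factors FGF2 and EGF and with heparin. Plasmids carrying a short hairpin RNA (shRNA, which lowers RNAs of matching sequence) and EGFP were introduced, and GFP-positive cells were sorted 3 days later. The labels name TRIZOL for the RNA and a SMART-seq2-type method for the libraries, a full-length cDNA method, and they do not say whether strand was kept. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that replicates of a group came from separate cultures, so all p-values measure only the spread between these samples, which may be technical.

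The main table holds an expected count (an estimated count of reads) per transcript and library, which the authors made with cutadapt, RSEM and the genome build mm10 and deposited without normalization. The submitters' processing notes name these tools with neither role nor order. Their versions, the annotation release and the settings are not given in the sources used here. Of the values in the table, 44.9% were 0, and 8.71% of those above 0 were whole numbers to within rounding error. The table has 111462 transcript rows and 1 blank row, and 110115 of the transcripts have a gene in GENCODE M21, whose build GRCm38 is the one that mm10 names. The counts of these were summed to 34910 genes and rounded to whole numbers. The other 1347 transcripts held between 0.595% and 0.650% of a library's counts and were left out of library sizes and tests.

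A second table holds the authors' own mixed model of an effect of young LINE-1, with 1 row per gene. It gives an estimate and its error, which are on a scale that is not named, a t score and a p-value for a group term, per the file headers. It also gives an adjusted p-value, which is 1 for all of its 17921 genes. The tool and the samples behind that model are not given in the sources used here. Its values are printed as the authors' values only.

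Genes with low counts were removed with filterByExpr of edgeR at its minimum count of 10, which left 15141 genes. Library sizes were scaled with TMM factors, and 1 model of the 5 groups was fitted to all libraries with edgeR's quasi-likelihood method with robust dispersions, so that the groups share 1 estimate of the spread. Each comparison was a contrast of that model, and p-values were adjusted with the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05. The common biological coefficient of variation was 0.158. CPM values are counts relative to the TMM-scaled library size, and log2 CPM used a prior count of 2. The tools were R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, sva 3.50.0 and statmod 1.5.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

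The groups, the 8 comparisons, 23 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists cover cell types, the cell cycle, stress and signalling responses, LINE-1 restriction, metabolism, ribosomes and histones. Each list was tested with camera of limma, which compares its members with all other genes, with a preset correlation between genes of 0.01, and the p-values were adjusted over the 23 lists. The same test was repeated with a correlation estimated from each list. The number of members called was counted once with the p-values adjusted over all genes and once adjusted over the list alone.

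In the 5 main comparisons the rule names up to 8 genes per direction, those with the largest log2 fold change among the genes called, with a mean log2 CPM of at least 3, with every library of 1 side beyond every library of the other, and with a symbol that is not a predicted-gene or clone name. It also names, for each list called, the 3 members with the smallest p in the direction of the list, and 12 marker genes whatever their result. Where fewer than 5 genes met the first part, the 5 genes with the smallest p are given as values. In the other 3 comparisons it names up to 5 genes per direction. The largest of these and the list members that pass the test are given here, and the rest are summarised. With 3 libraries against 3, groups that do not overlap occur by chance for 10% of genes.

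The alternatives were RLE in place of TMM scaling, library size with no scaling factor, no filter, a filter of at least 50 counts in at least 3 libraries, libraries thinned to the smallest total, DESeq2, limma-voom with quality weights, only the compared groups in the fit, the replicate number as a block, the last number of the library description (1 or 12) as a covariate, and leaving out each library in turn. Where a library was left out, 2 libraries of its group remained. A run without 2 libraries that stand apart, 1 surrogate variable from sva, and 1 more contrast for the deposited table were added after the data had been seen. The scripts were tested on simulated data for shLINE_Orf1 against shControl over 15141 genes. There 40% of genes changed 1.5-fold, 84% of those changed 2-fold and 100% of those changed 3-fold or 4-fold were recovered, with 5 false calls.

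Comparisons that share libraries also share chance values. For these, 20 simulations with every group unchanged, and libraries shared in the same way, gave the overlap, correlation and covariance with no effect. There were 20 more without the 2 libraries that stand apart. A test with separate shControl libraries was added after the data had been seen. Genes that share reads with near-identical copies (the replication-dependent histones, Ifit3 and Ifit3b, H2-D1 and other class I genes) are uncertain, because the estimated counts can divide such reads between copies. Overlapping and antisense genes are uncertain as well, because the strand is not stated. A test of 1 explanation rests on a withheld item and is not reported here. The median standard error of a log2 fold change was between 0.148 and 0.172, depending on the comparison.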

Results

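RNA of sorted mouse neural progenitor cells was sequenced 3 days after shRNA plasmids were introduced. LINE-1 elements are retrotransposons, repeats that copy themselves through RNA. Per the series' design text, shRNAs against young and against old LINE-1 were used, and a full-length LINE-1 was introduced together with the shRNA against young LINE-1. The groups are shControl, shLINE_Orf1, shLINE_Orf2, shLINE_MdV_I and shLINE_Orf1 with LINE-1 (shLINE_Orf1+LINE-1), each with 3 libraries. The labels pair the added LINE-1 with shLINE_Orf1, and they do not state whether shLINE_Orf2 and shLINE_MdV_I target young or old elements. The libraries held between 39204327 and 51070601 gene counts. Replicates of a group differed by more than counting noise in every pair, with a chi-square per degree of freedom between 7.32 and 261.

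The knockdown target itself comes first in such a design. LINE-1 transcripts were not analysed here, since the table used counts annotated gene transcripts, and so the extent of the knockdown in each library was not measured. EGFP and the plasmids were not analysed here either.

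Cell type markers were those of a progenitor culture. In shControl the progenitor genes Sox2 and Nes were at 203 and 363 CPM and the glial progenitor factor Olig2 at 758 CPM, while the neuronal genes Dcx, Tubb3 and Neurod1 were at 6.06, 9.86 and 0.617 CPM (means, n = 3). Of 12 marker genes fixed in advance (these 6 and Pax6, Hes5, Gfap, Mki67, Cdkn1a and Isg15), none was called by edgeR's quasi-likelihood test in the 4 comparisons with shControl of single groups. The smallest Benjamini-Hochberg adjusted p there was 0.0609, for the interferon-induced Isg15 in shLINE_MdV_I, with a log2 fold change of -0.56 ± 0.13. In shLINE_Orf1 and shLINE_Orf2 the smallest belonged to Neurod1, a neuronal transcription factor, with log2 fold changes of -1.46 ± 0.47 (adjusted p = 0.325) and -1.33 ± 0.46 (adjusted p = 0.445).

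Genes of mitochondria, ribosomes and histones also set single libraries apart. The first principal component of log2 CPM held 23.9% of the variance. It placed shLINE_Orf1 replicate 1 at 75.9 and shControl replicate 2 at 24.3, and the other 13 libraries lay between -18.8 and 4.72. On the second component, with 9.18% of the variance, shControl replicate 1 lay lowest, at -31.5. The median Spearman correlation with the other libraries was 0.974 for shLINE_Orf1 replicate 1, 0.989 for shControl replicate 2 and at least 0.991 for the rest. Mitochondrially encoded mRNAs took 3.61% of counts in shLINE_Orf1 replicate 1 and 2.02% in shControl replicate 2, against 1.36% to 1.97% elsewhere. Counts assigned to Lars2, the top gene in every library and annotated as a mitochondrial leucyl-tRNA synthetase, were 5.88% and 4.62% there and at most 3.82% elsewhere. Mitochondrial rRNA genes held no counts in any library. Whether all counts assigned to Lars2 come from its own mRNA is therefore not known. Counts without shLINE_Orf1 replicate 1 and shControl replicate 2, 2 libraries chosen after the data had been seen, are given beside each count of genes. Such counts keep shControl replicate 1.

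**Figure D1:**
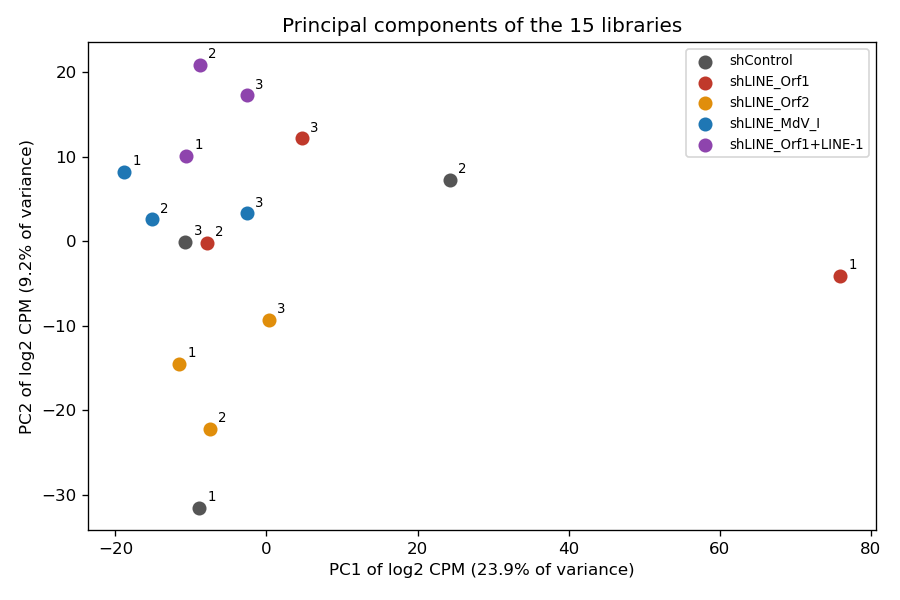
First and second principal components of log2 CPM for the 15 libraries, coloured by group and numbered by replicate, with the percent of variance on each axis. shLINE_Orf1 replicate 1 lies at 75.9 and shControl replicate 2 at 24.3 on the first component, apart from the other libraries.

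Comparing shLINE_Orf1 with shControl asks what the shRNA that was paired with added LINE-1 does on its own. Cryab, which encodes the small heat shock protein alpha B-crystallin (chromosome 9, 50751325 to 50756636, GRCm38), rose from 19.7 ± 1.2 to 60.7 ± 8.3 CPM (SD, n = 3 each). Its log2 fold change was 1.62 ± 0.11 (SE; adjusted p = 4.82e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Rab3b, a small GTPase of secretory vesicles (chromosome 4, 108879063 to 108943324), rose from 247 ± 13 to 425 ± 19 CPM (log2 fold change 0.78 ± 0.09). The proteasome subunit Psmb6 rose by 1.02 ± 0.17 on the log2 scale, the secretory pathway genes Tmed3 and Sec13 by 0.83 and 0.69, the myosin light chain Myl9 by 0.75, the glutathione transferase Gstt1 by 0.87 and Cend1, a gene of neuronal cell cycle exit, by 0.93. The linker histone gene Hist1h1c (chromosome 13, 23738808 to 23740367) fell by 0.95 on the log2 scale with an error of 0.17, from 145 ± 27 to 75.1 ± 22 CPM. The actin-severing Gsn, Cpne1 and the secreted Mfge8 fell as well (log2 fold changes -0.69, -0.72 and -0.43). In all, 21 genes were higher and 6 lower of 15141 tested, and 1596 had an unadjusted p under 0.05, where chance gives 757. Without the 2 libraries that stand apart, 100 were higher and 39 lower. The count was 13 without shControl replicate 1, 5 without shControl replicate 3 and 12 without shLINE_Orf1 replicate 3. It was 1 with only the compared groups in the fit and 4 with the replicate number as a block. Cryab passed under all 18 alternatives, at adjusted p of at most 0.0407, and Rab3b under all but the fit with only the compared groups. The other 10 genes named passed under 10 (Mfge8) to 14 of the 18.

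Several lists moved in shLINE_Orf1 with few single genes past the test. All 74 nuclear genes of oxidative phosphorylation had positive log2 fold changes (median 0.36, camera adjusted p = 8.05e-15; adjusted p = 0.686 with an estimated correlation). So did the 80 ribosomal protein genes (median 0.27, adjusted p = 1.89e-07; adjusted p = 0.734 with an estimated correlation) and the 12 mitochondrially encoded genes (median 0.52, adjusted p = 0.00604; adjusted p = 0.734 with an estimated correlation). No member of these lists was called, over all genes or adjusted over the list alone. Cox4i1, a subunit of cytochrome oxidase, had a log2 fold change of 0.80 ± 0.22 (quasi-likelihood adjusted p = 0.211), Rpl11 0.59 ± 0.23 and mt-Co1 0.53 ± 0.25. The means of the oxidative phosphorylation list in the shLINE_Orf1 libraries were 0.82, -0.04 and 0.18 relative to shControl, highest in the library that stands apart, and those of the shControl libraries -0.25, 0.39 and -0.15, highest in the other that stands apart. Without shLINE_Orf1 replicate 1 its camera adjusted p was 0.0499, and the ribosomal and mitochondrially encoded lists turned direction (adjusted p = 0.125 and 0.138). Without both libraries that stand apart the oxidative phosphorylation and ribosomal lists were higher (adjusted p = 1.35e-25 and 7.30e-08), as they were without shControl replicate 2 alone (4.75e-27 and 2.21e-18), and the mitochondrially encoded list was not called without both (0.502). The ribosomal list also lost its call without shControl replicate 1 (adjusted p = 0.224) and the mitochondrially encoded list without shControl replicate 3 (adjusted p = 0.0694).

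Of the other lists in shLINE_Orf1, G2/M genes of mitosis were higher (54 of 71 positive, median 0.12, camera adjusted p = 4.49e-05; adjusted p = 0.433 with an estimated correlation). Their means in the 3 libraries were 0.23, 0.06 and 0.02, highest in the library that stands apart, and without it the adjusted p was 0.00547. Lower lists were neuronal differentiation (33 of 44 negative, median -0.21, adjusted p = 0.00547; adjusted p = 0.433 with an estimated correlation), oligodendrocyte lineage (17 of 23 negative, adjusted p = 0.0124; 0.686 as the adjusted p with an estimated correlation), LINE-1 restriction and heterochromatin (37 of 54 negative, adjusted p = 0.0124; adjusted p = 0.433 with an estimated correlation) and immediate early genes (26 of 34 negative, adjusted p = 0.0179; adjusted p = 0.734 with an estimated correlation). No member was called, over all genes or adjusted over the list alone. Gad1, which makes the transmitter GABA, had a log2 fold change of -0.67 ± 0.19 (quasi-likelihood adjusted p = 0.211), and the 5-methylcytosine oxidase Tet2 -0.39 ± 0.12. Without shLINE_Orf1 replicate 1 none of these 4 lower lists was called (camera adjusted p = 0.130, 0.130, 0.181 and 0.290), and the immediate early list turned direction. The oligodendrocyte list was not called without shControl replicate 3 either (adjusted p = 0.0909), nor the immediate early list without shControl replicate 2 or 3 (adjusted p = 0.0696 and 0.0909). Without shLINE_Orf1 replicate 1, 5 lists were called in place of 8.

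In shLINE_Orf2 against shControl, Cryab rose again, by 0.96 ± 0.11 on the log2 scale to 38.4 ± 2.1 CPM (adjusted p = 0.00416, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Mavs, an adaptor of RNA sensing at mitochondria, rose by 0.81, Banp by 0.74, Rab3b and Desi1 by 0.60 each, the acetyl-CoA synthetase Acss2 by 0.55, Hbs1l by 0.53 and the proton pump subunit Atp6v1b2 by 0.47. Hist1h1c fell to 56.3 ± 3.5 CPM (log2 fold change -1.37 ± 0.17), and another histone gene, Hist1h2bc, fell too (-1.17). So did the protease inhibitor Serpinb1a, the integrin Itga4, Pqlc3, Gsn, Efhd2 and the growth factor Gas6 (log2 fold changes -1.20, -1.03, -0.98, -0.92, -0.85 and -0.67). There were 12 higher and 17 lower genes, or 19 and 14 when libraries were scaled by their size only. At unadjusted p under 0.05 there were 1061 genes. Without the 2 libraries that stand apart, 133 were higher and 139 lower. The count fell to 13, 9 and 5 without shControl replicates 1, 2 and 3, and to 5, 3 and 11 without shLINE_Orf2 replicates 1, 2 and 3. Cryab and Hist1h1c passed under all 18 alternatives (adjusted p of at most 0.0340 and 0.0481), Gsn under 17, and the other genes named under 8 (Atp6v1b2 and Hbs1l) to 14.

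The p53 target list was lower in shLINE_Orf2, and this held with both correlations. Of 40 members, 29 were negative, with a median log2 fold change of -0.13 (camera adjusted p = 2.15e-05; adjusted p = 0.00643 with an estimated correlation). It stayed lower in all 12 alternatives. No member was called over all genes, and 6 were lower when adjusted over the list alone. Dcxr, a carbonyl reductase, had a log2 fold change of -0.89 ± 0.19 (quasi-likelihood adjusted p = 0.0891) and the apoptosis gene Pmaip1 -0.45 ± 0.11, while the cell cycle inhibitor Cdkn1a stood at -0.12 ± 0.11. The means of the list were -0.17, -0.16 and -0.13 in the 3 libraries and between -0.02 and 0.02 in shControl.

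Glycolysis and hypoxia genes were higher in shLINE_Orf2 (35 of 36 positive, median 0.35, camera adjusted p = 8.53e-16; adjusted p = 0.352 with an estimated correlation). The collagen prolyl hydroxylase P4ha2 rose by 1.79 ± 0.32, and 5 members were higher when adjusted over the list alone. The library means of the list were 0.80, 0.37 and -0.04, so replicate 1 carried most of it and replicate 3 none. Histone genes were lower (56 of 62 negative, median -0.40, adjusted p = 5.33e-11; adjusted p = 0.471 with an estimated correlation), with Hist1h1c and Hist1h2bc called over all genes and 4 lower adjusted over the list alone. Histone means in shControl ranged from -0.42 to 0.41, highest in the replicate that stands apart. G2/M genes (59 of 71 positive, adjusted p = 6.25e-07) and cholesterol synthesis genes (25 of 30 positive, adjusted p = 0.000282) were higher, each with adjusted p = 0.352 with an estimated correlation. Nucleolar genes were lower (63 of 73 negative, adjusted p = 0.000523; adjusted p = 0.414 with an estimated correlation). Genes of the integrated stress response were higher (30 of 49 positive, adjusted p = 0.0472; adjusted p = 0.651 with an estimated correlation). No member of these 4 lists was called over all genes, and adjusted over the list alone 1 stress response gene was higher. The nucleolar call ended without shControl replicate 3 (adjusted p = 0.0642), and the stress response call without shControl replicate 1 or shLINE_Orf2 replicate 3 (adjusted p = 0.665 and 0.259).

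shLINE_MdV_I against shControl had 39 genes higher and 51 lower by edgeR's quasi-likelihood test, more than the other 3 groups had by that test. Interferon response genes fell together. Irf7, the transcription factor that amplifies type I interferon (chromosome 7, 141262706 to 141266481), fell from 36.2 ± 6.6 to 15.2 ± 0.52 CPM, a log2 fold change of -1.25 ± 0.18 (adjusted p = 0.00422, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3 each). Ifit3b and Ifit3, antiviral genes that share near-identical sequence, fell (log2 fold changes -1.15 and -1.02), as did the guanylate-binding Gbp6 (-1.25). H2-D1, a class I histocompatibility gene (chromosome 17, 35262730 to 35267499), fell from 490 ± 85 to 266 ± 20 CPM (-0.88 ± 0.13). Of 56 list members, 52 were negative and the median was -0.44 (camera adjusted p = 7.54e-36; adjusted p = 0.0222 with an estimated correlation). Over all genes 10 members were lower (Irf7, Ifit3, Ifit3b, H2-D1, B2m, Bst2, Ifi35, Irgm1, Oas1a and Igtp), and 28 were lower adjusted over the list alone. The list means of the shLINE_MdV_I libraries were -0.53, -0.46 and -0.49, below all 12 other libraries, whose lowest was -0.20. The list stayed lower in all 12 alternatives.

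Some genes of neurons were higher and some genes of astrocytes lower in shLINE_MdV_I, though neither list was called with an estimated correlation. Stmn4, a neuronal regulator of microtubules (chromosome 14, 66344296 to 66361680), rose from 5.07 ± 0.62 to 10.9 ± 0.80 CPM (1.10 ± 0.16), and the synaptic fusion protein Snap25 rose by 0.83 ± 0.15. The synaptic gene Cplx1, from 15.4 ± 0.87 to 32.9 ± 2.9 CPM, and Rgs16, a regulator of G protein signalling, rose by 1.10 and 1.22. Prss23, Sarm1, Mavs, Dgkg, Mtmr11 and Cpox rose by 0.95, 0.77, 0.73, 0.73, 0.73 and 0.69. The astrocyte genes Sparcl1, from 429 ± 44 to 230 ± 19 CPM, Apoe, a lipid carrier, and Aldh1a1, a retinaldehyde dehydrogenase, fell (log2 fold changes -0.90, -1.16 and -1.75). The neuronal list had 28 of 44 members positive, 2 of them called and 8 higher adjusted over the list alone (camera adjusted p = 7.67e-05; adjusted p = 0.273 with an estimated correlation). The astrocyte list had 25 of 33 negative, with 1 called higher and 4 lower, and 2 higher and 6 lower adjusted over the list alone (camera adjusted p = 7.67e-05; adjusted p = 0.273 with an estimated correlation). Neural progenitor genes were higher (23 of 34 positive, median 0.11, adjusted p = 0.0206; adjusted p = 0.733 with an estimated correlation), with no member called over all genes or adjusted over the list alone, and without shLINE_MdV_I replicate 3 that call ended (adjusted p = 0.0586).

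Histone genes were lower in this group as well, though their list was not called with an estimated correlation. Hist1h2bc fell from 241 ± 71 to 63.5 ± 5.5 CPM (log2 fold change -1.93) and Hist1h1c to 39.6 ± 4.0 CPM (-1.87), and Hist2h3c1 fell too (-1.32). Of 62 members, 57 were negative, 6 were called and 14 were lower adjusted over the list alone (camera adjusted p = 2.51e-17; adjusted p = 0.273 with an estimated correlation). The members are short, with a median exonic length of 579 bases against 4334 for all genes tested. Deviations of shControl replicates 1 and 2 correlated with exonic length at 0.393 and -0.472. Whether length plays a part in the histone shifts between groups was not tested. Serpinb1a fell (-1.41). Smaller shifts were seen in genes of cholesterol synthesis (27 of 30 positive, adjusted p = 9.83e-05; adjusted p = 0.273 with an estimated correlation), glycolysis and hypoxia (34 of 36 positive, adjusted p = 7.67e-05; adjusted p = 0.733 with an estimated correlation), the integrated stress response (37 of 49 positive, adjusted p = 0.00107; adjusted p = 0.406 with an estimated correlation) and the mitochondrial genome (0 of 12 positive, adjusted p = 0.0128; adjusted p = 0.790 with an estimated correlation). The amino acid enzyme Cbs rose by 0.43. Of these 4 lists it was the only member called over all genes, and 2 stress response genes were higher adjusted over the list alone. The mitochondrial list was not called without shControl replicate 2 (adjusted p = 0.429), shLINE_MdV_I replicate 1 (0.0808) or shLINE_MdV_I replicate 2 (0.0584), nor the stress response list without shControl replicate 1 (adjusted p = 0.0851).

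At unadjusted p under 0.05 there were 1307 genes for shLINE_MdV_I, and without the 2 libraries that stand apart 172 genes were higher and 217 lower. The count was 43 and 57 without shControl replicates 1 and 2, and 22, 28 and 30 without shLINE_MdV_I replicates 1, 2 and 3. Irf7, Ifit3b, H2-D1, Cplx1, Stmn4, Prss23, Mtmr11, Sparcl1, Hist1h1c and Hist1h2bc passed edgeR's quasi-likelihood test under all 18 alternatives, with a highest adjusted p of 0.0472 among them. The other called genes given with a log2 fold change of their own passed under 9 (Cpox) to 16.

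**Figure D2:**
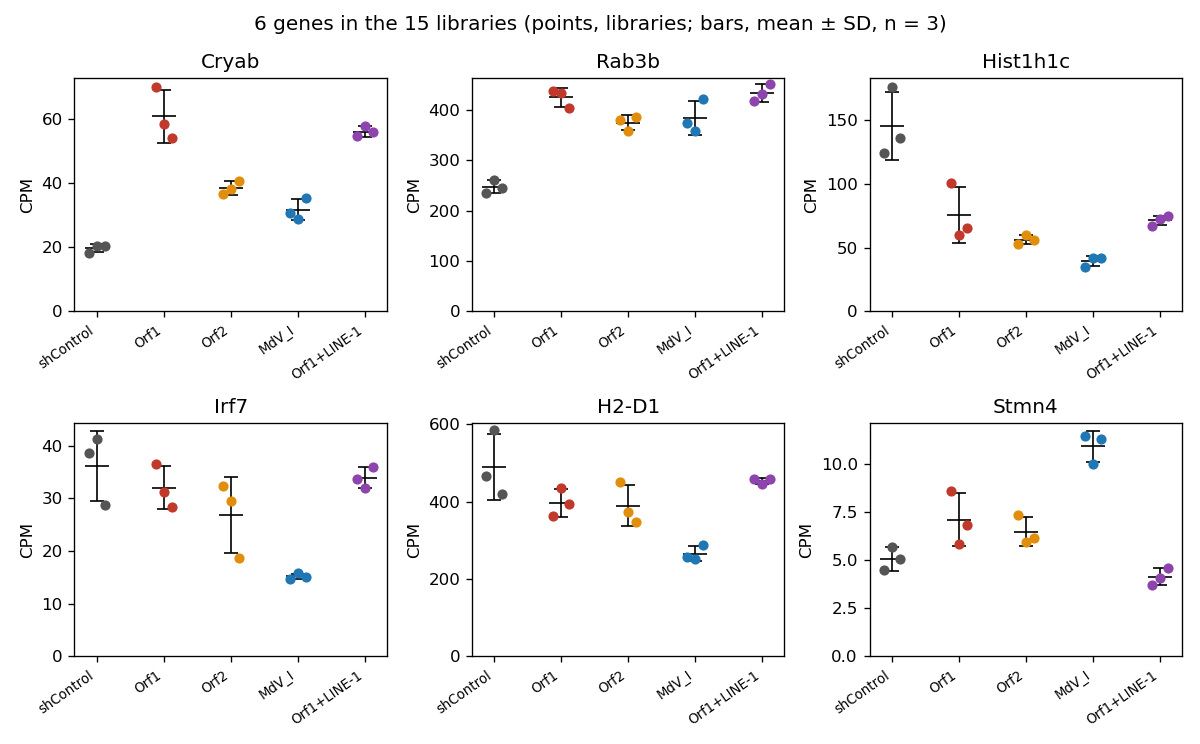
CPM of 6 genes in each of the 15 libraries by group, with points for libraries and bars for the mean ± SD (n = 3), on axes that start at 0. Cryab and Rab3b lie above shControl and Hist1h1c below it in the other 4 groups, and Irf7 and H2-D1 are lowest and Stmn4 highest in shLINE_MdV_I.

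The mean of shLINE_Orf1 and shLINE_Orf2 against shControl was set as the effect of the pair of shRNAs. Cryab rose by 1.29 ± 0.10 (adjusted p = 2.64e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Psmb6 by 0.88, Mavs by 0.73, Tmed3 by 0.71, Rab3b by 0.69, Banp and Gpbp1l1 by 0.65 and Bloc1s5 by 0.63. The histone genes Hist1h1c and Hist1h2bc fell (log2 fold changes -1.16 and -1.06), and so did Hist2h3c1 (adjusted p = 0.0355). Gsn, Efhd2, Gas6, Gas7, Cpne1 and the splicing factor Snrpa1 fell as well (-0.80, -0.79, -0.55, -0.51, -0.51 and -0.45). In all 28 genes were higher and 17 lower, with 1204 at unadjusted p under 0.05, and without the 2 libraries that stand apart 155 were higher and 137 lower. The count was 18 and 6 without shControl replicates 1 and 3, 93 without shLINE_Orf1 replicate 1, and 29, 15 and 15 without shLINE_Orf2 replicates 1, 2 and 3. Cryab passed under all 21 alternatives, and Rab3b, Hist1h1c and Gsn under 20. Hist1h2bc passed under 17, Efhd2, Gas6, Mavs, Banp and Psmb6 under 15, Tmed3 under 14, Gpbp1l1 and Bloc1s5 under 13, Gas7 and Cpne1 under 12, Hist2h3c1 under 11 and Snrpa1 under 9.

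For that mean, G2/M genes (59 of 71 positive, camera adjusted p = 8.29e-08; adjusted p = 0.566 with an estimated correlation) and glycolysis and hypoxia genes (32 of 36 positive, adjusted p = 3.97e-07; adjusted p = 0.622 with an estimated correlation) were higher. Histone genes were lower (41 of 62 negative, 4 called and 4 adjusted over the list alone, adjusted p = 6.53e-05; adjusted p = 0.718 with an estimated correlation), and without shControl replicate 2 the adjusted p was 0.863, without shLINE_Orf1 replicate 2 0.0581. Nuclear oxidative phosphorylation genes, all 74 positive (adjusted p = 3.84e-07; adjusted p = 0.719 with an estimated correlation), were not called without shLINE_Orf1 replicate 1 (adjusted p = 0.235) or without shControl replicate 1 (adjusted p = 0.286), but were higher without shControl replicate 2 (adjusted p = 4.07e-22) and without both libraries that stand apart (2.70e-25). Of the remaining 5 lists called, ribosomal and cholesterol genes were higher and nucleolar, immediate early and neuronal genes lower, at camera adjusted p between 0.00571 and 0.0331, and between 0.622 and 0.897 as the adjusted p with an estimated correlation. The neuronal, immediate early and nucleolar lists were not called without shControl replicate 3 (adjusted p = 0.186 each), nor the cholesterol list without shControl replicate 1 (adjusted p = 0.127). Without shLINE_Orf1 replicate 1, the library that stands apart, the neuronal and immediate early lists had adjusted p of 0.305 and 0.734, and without shControl replicate 2 they had 0.115 and 0.0742 and the cholesterol list 0.176. The nucleolar call also ended without shLINE_Orf1 replicate 2 (adjusted p = 0.187), the cholesterol call without shLINE_Orf1 replicate 3 (0.128), the immediate early call without shLINE_Orf2 replicate 2 or 3 (0.0684 and 0.119) and the ribosomal call without shControl replicate 3 or shLINE_Orf2 replicate 3 (0.166 and 0.119). The ribosomal list turned direction without shControl replicate 1 (adjusted p = 0.107) and without shLINE_Orf1 replicate 1 (adjusted p = 0.240), and it was higher without shControl replicate 2 (3.69e-15) and without both libraries that stand apart (3.57e-11). Without shLINE_Orf1 replicate 1, 5 lists were called in place of 9. Among these lists, beyond the histones, 1 glycolysis gene was higher adjusted over the list alone and none was called over all genes.

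The same mean was compared with shLINE_MdV_I, a direct test of whether the shRNAs differ. Interferon genes were higher under shLINE_Orf1 and shLINE_Orf2: Ifi27l2a by 1.28 ± 0.21 (adjusted p = 0.0126, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Irf7 by 0.95 ± 0.16 and Ifit3b by 0.91 ± 0.15. The list had 49 of 56 members positive, 13 called and 33 higher adjusted over the list alone (median 0.47, camera adjusted p = 1.85e-36; adjusted p = 0.0198 with an estimated correlation). Neuronal genes were lower, with 37 of 44 negative, 4 called (Btg2, Stmn4, Ina and Neurod1) and 12 lower adjusted over the list alone (median -0.23, camera adjusted p = 7.31e-12; adjusted p = 0.0285 with an estimated correlation). Both lists kept direction and call in all 15 alternatives. Rgs16, Dapk1, a calcium-dependent kinase, the neuronal vesicle coat subunit Ap3b2, Cplx1 and Igsf21 were lower by log2 fold changes of -1.26, -0.81, -0.80, -0.73 and -0.69, and Hist1h2bc and Tmem14a were higher by 0.87 and 0.86.

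In all 39 genes were higher and 31 lower in that comparison, with 1407 at unadjusted p under 0.05, and without the 2 libraries that stand apart 135 were higher and 121 lower. The count was 40 and 29 without shLINE_Orf2 replicates 1 and 2, and 11, 12 and 19 without shLINE_MdV_I replicates 1, 2 and 3. Cplx1 passed under all 21 alternatives (quasi-likelihood adjusted p of at most 0.0484), Rgs16 under 20 and the other genes given with a log2 fold change under 12 (Dapk1) to 18. Astrocyte genes were higher (25 of 33 positive, Apoe, Sparcl1 and Agt called, 8 adjusted over the list alone, camera adjusted p = 1.98e-07; adjusted p = 0.0908 with an estimated correlation). Histone, nuclear oxidative phosphorylation, mitochondrially encoded, ribosomal and G2/M lists were higher and oligodendrocyte, stress response, immediate early, neural progenitor and p53 lists lower, at camera adjusted p between 7.31e-12 and 0.0139, and between 0.0816 and 0.552 as the adjusted p with an estimated correlation. The ribosomal and immediate early lists were not called without shLINE_Orf1 replicate 1 (adjusted p = 0.493 and 0.282), nor p53 targets without shLINE_Orf1 replicate 3 or shLINE_MdV_I replicate 3 (adjusted p = 0.0687 and 0.110). In these 10 lists Hist1h2bc was called higher and Fosl1, Btg2 and Cd80 lower over all genes, and adjusted over the list alone 4 histone and 1 G2/M genes were higher and 4 p53, 1 oligodendrocyte and 1 immediate early genes lower.

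**Figure D3:**
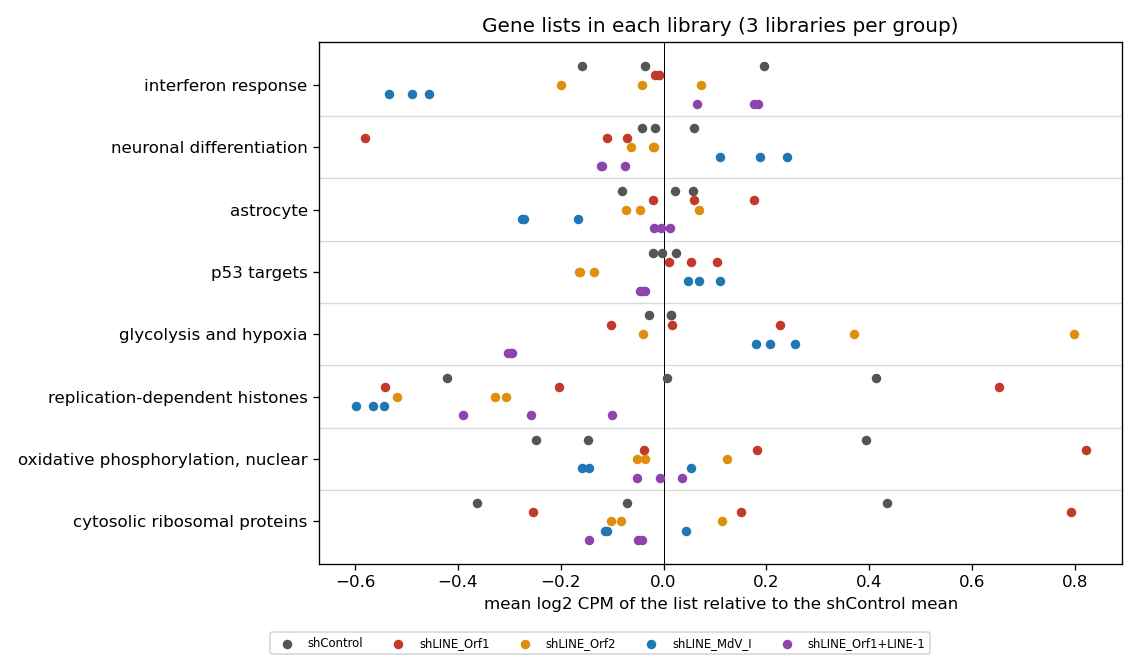
Mean log2 CPM of 8 gene lists in each library relative to the shControl mean, with 1 point per library, 3 libraries per group and colours for the groups. The shLINE_MdV_I libraries lie lowest for interferon response genes (-0.53, -0.46 and -0.49), and shLINE_Orf1 replicate 1 lies highest for oxidative phosphorylation and ribosomal genes.

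Adding full-length LINE-1 to shLINE_Orf1 asks which effects of that shRNA a LINE-1 can offset. Ankrd37, a gene induced by low oxygen, was at 11.5 ± 4.0 CPM with shLINE_Orf1 and at 2.31 ± 0.50 CPM with added LINE-1 (log2 fold change -2.31 ± 0.33, adjusted p = 0.0523, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). With added LINE-1 Ankrd37 was also lower than in shControl, as given below, so its fall went beyond a return to the shControl level. The next smallest p-values belonged to the muscle cytoskeletal gene Pdlim3 (-1.47 ± 0.23), Narf (-0.78 ± 0.15), Reg2 (1.83 ± 0.37) and the zinc finger gene Zfp983 (-1.21 ± 0.25), with adjusted p of 0.0968 for Pdlim3 and 0.394 for the other 3. The number of genes called by edgeR's quasi-likelihood test was 0, with 1680 at unadjusted p under 0.05. It was also 0 without the 2 libraries that stand apart, 1 without shLINE_Orf1 replicate 3 or with thinned libraries, 20 by DESeq2 and 397 by limma-voom with quality weights. None of the 12 marker genes was called, and Sox2 and Nes had log2 fold changes of 0.05 ± 0.11 and 0.22 ± 0.21.

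Glycolysis and hypoxia genes were lower with added LINE-1 than with shLINE_Orf1 alone (31 of 36 negative, 11 lower adjusted over the list alone, median -0.35, camera adjusted p = 2.91e-09; adjusted p = 0.589 with an estimated correlation). This list was not called in shLINE_Orf1 against shControl. With added LINE-1 it was also lower than in shControl, so its fall went beyond a return to the shControl level. Adm and Ddit4, both induced by low oxygen, had log2 fold changes of -0.86 ± 0.23 and -0.68 ± 0.19. Interferon genes were higher (41 of 56 positive, 2 higher adjusted over the list alone, median 0.13, adjusted p = 0.000975; adjusted p = 0.589 with an estimated correlation), with Oasl1 at 0.61 ± 0.15. Genes of DNA replication were higher (36 of 59 positive, median 0.12, adjusted p = 0.00593; adjusted p = 0.589 with an estimated correlation) and p53 targets lower (28 of 40 negative, 2 adjusted over the list alone, median -0.10, adjusted p = 0.0104; adjusted p = 0.170 with an estimated correlation). Both of these calls ended without shLINE_Orf1 replicate 2 (adjusted p = 0.559 and 0.181). No list member was called over all genes.

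Of the other 9 lists called there, nuclear oxidative phosphorylation, ribosomal, mitochondrially encoded, histone and G2/M genes were lower and immediate early, neural progenitor, nucleolar and LINE-1 restriction genes higher, at camera adjusted p between 2.26e-14 and 0.0422, and between 0.589 and 0.680 as the adjusted p with an estimated correlation. Adjusted over the list alone, 1 immediate early gene was higher and 1 lower. Without shLINE_Orf1 replicate 1, 7 lists were called in place of 13, the mitochondrially encoded, histone and immediate early lists turned direction (adjusted p = 0.653, 0.155 and 0.940), the ribosomal, LINE-1 restriction and neural progenitor lists had adjusted p of 0.444, 0.444 and 0.653, and the G2/M list was not called. Nuclear oxidative phosphorylation genes stayed lower and nucleolar genes higher without shLINE_Orf1 replicate 1 (adjusted p = 0.00327 and 0.000179) and without both libraries that stand apart (2.83e-05 and 2.34e-05). The nucleolar call ended without shLINE_Orf1 replicate 2 (adjusted p = 0.807).

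Against shControl, Cryab and Rab3b were called in cells with shLINE_Orf1 and added LINE-1 as they were without the added LINE-1. Cryab rose to 55.9 ± 1.6 CPM (1.51 ± 0.11, adjusted p = 1.33e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and Rab3b to 433 ± 17 CPM (0.81 ± 0.09). Myl9, the cyclin Ccnyl1 and Desi1 rose by 0.86, 0.73 and 0.62. Ankrd37, Hist1h2bc, Hist1h1c, the cytoskeletal regulator Cdc42ep3 and Gsn fell (log2 fold changes -2.02, -1.24, -1.03, -0.81 and -0.79). There were 11 higher and 10 lower genes, or 13 and 7 when libraries were scaled by their size only, and 1327 at unadjusted p under 0.05. Without the 2 libraries that stand apart 202 were higher and 151 lower, and the count was 3 without shControl replicate 3 and 2 without any 1 of the 3 libraries with added LINE-1. Cryab and Rab3b passed under all 18 alternatives, and the other genes named under 10 (Gsn) to 13.

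In that comparison, genes of DNA replication were higher (47 of 59 positive, 3 higher adjusted over the list alone, median 0.16, camera adjusted p = 5.24e-08; adjusted p = 0.164 with an estimated correlation). Glycolysis and hypoxia genes were lower, with Ankrd37 called and 4 lower adjusted over the list alone (30 of 36 negative, median -0.19, adjusted p = 2.81e-07; adjusted p = 0.573 with an estimated correlation). The list means of the 3 libraries were -0.29, -0.30 and -0.30, below all others. Histone genes were lower (51 of 62 negative, 2 called, 4 lower adjusted over the list alone) and interferon genes higher (41 of 56 positive), both at adjusted p = 9.77e-05 and, as the adjusted p with an estimated correlation, 0.573. Without shControl replicate 2 the histone call ended (adjusted p = 0.480), and without shControl replicate 3 the interferon call (adjusted p = 0.187). Genes of NF-kB inflammation, called in no other comparison (15 of 21 positive, adjusted p = 0.0260; adjusted p = 0.573 with an estimated correlation), lost the call without shControl replicate 3 (adjusted p = 0.159). The other 5 lists called, neuronal, oligodendrocyte and stress response genes lower and cholesterol and G2/M genes higher, had camera adjusted p between 0.0185 and 0.0482, and 0.573 as the adjusted p with an estimated correlation. Each was lost without at least 1 library, with adjusted p of 0.159, 0.363, 0.510 and 0.368 for neuronal, oligodendrocyte, stress response and G2/M genes without shControl replicate 3 and 0.106 for cholesterol genes without shControl replicate 1. Adjusted over the list alone, 1 neuronal, 2 oligodendrocyte and 2 stress response genes were lower and 1 stress response and 1 cholesterol genes higher. Without shControl replicate 3, 5 lists were called in place of 10.

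shLINE_Orf2 was also compared directly with shLINE_Orf1. p53 targets were lower with shLINE_Orf2, with 29 of 40 members negative and 14 lower adjusted over the list alone (median -0.13, camera adjusted p = 2.30e-07; adjusted p = 0.00164 with an estimated correlation). Oxidative phosphorylation, ribosomal, mitochondrially encoded, histone and DNA replication lists were also lower and glycolysis, stress response, neuronal, oligodendrocyte, cholesterol and LINE-1 restriction lists higher, at camera adjusted p between 3.05e-13 and 0.0264, and between 0.469 and 0.585 as the adjusted p with an estimated correlation. Adjusted over the list alone, 1 stress response, 3 oligodendrocyte and 1 LINE-1 restriction genes were higher and 1 oligodendrocyte gene lower. No single gene was called by edgeR's quasi-likelihood test (0 genes, smallest adjusted p = 0.0596, 1729 at unadjusted p under 0.05). There were 5 and 1 without shLINE_Orf1 replicates 2 and 3, 11 with no filter, 125 by DESeq2, 840 by limma-voom and, without the 2 libraries that stand apart, 7 higher and 17 lower. Several of these lists moved with shLINE_Orf1 replicate 1. Means in its group were 1.26, 0.01 and -0.25 for mitochondrially encoded, 0.79, -0.25 and 0.15 for ribosomal, 0.65, -0.54 and -0.20 for histone and -0.58, -0.11 and -0.07 for neuronal genes. Without that library these 4 lists were not called (adjusted p = 0.807, 0.640, 0.640 and 0.279), the ribosomal list turned direction, and the oligodendrocyte and LINE-1 restriction lists were not called (adjusted p = 0.169 and 0.279). Oxidative phosphorylation genes had adjusted p = 0.0438 without it. Calls also ended without shLINE_Orf1 replicate 2 for stress response and cholesterol genes (adjusted p = 0.0804 and 0.178), without shLINE_Orf2 replicate 3 for cholesterol and LINE-1 restriction genes (0.0857 and 0.0715), and without shLINE_Orf2 replicate 1 for glycolysis and oligodendrocyte genes (0.0741 and 0.0501). The p53 target list stayed lower in all 12 alternatives. Of all 23 lists, 9 were called without shLINE_Orf1 replicate 1 in place of 12.

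**Figure D4:**
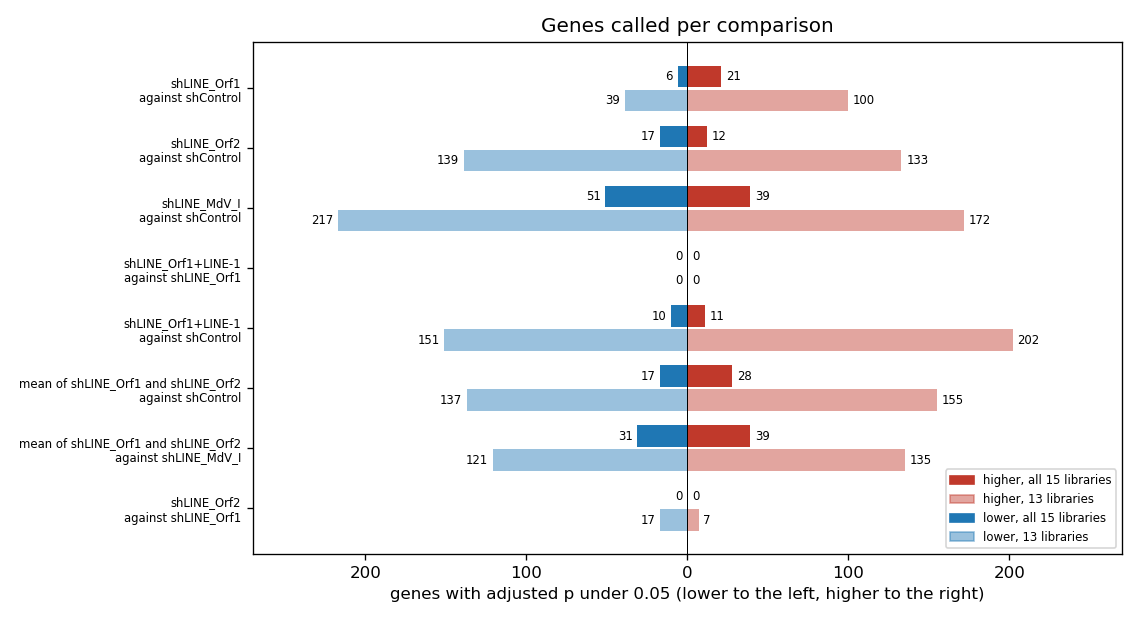
Genes called at adjusted p under 0.05 in each of the 8 comparisons, higher to the right and lower to the left, with dark bars for all 15 libraries and pale bars for the 13 left without shLINE_Orf1 replicate 1 and shControl replicate 2. shLINE_MdV_I against shControl has 39 higher and 51 lower genes with all libraries and 172 and 217 without these 2.

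Some genes were called in more than 1 group against shControl. Cryab, Rab3b, Atp6v1b2 and Desi1 were called higher and Hist1h1c and Mfge8 lower in all 4. The log2 fold changes of Atp6v1b2 were between 0.47 and 0.59, those of Desi1 between 0.54 and 0.62 and those of Mfge8 between -0.44 and -0.41. shLINE_Orf1 and shLINE_Orf2 shared 5 higher and 3 lower genes, where independent lists of their sizes would share 0.0166 and 0.00674. shLINE_Orf1 and shLINE_MdV_I shared 7 and 2 (0.0541 and 0.0202), among them Cbs and Prss23. shLINE_Orf2 and shLINE_MdV_I shared 7 and 7 (0.0309 and 0.0573), among them Mavs, Acss2, Hbs1l, Serpinb1a, Efhd2 and Hist1h2bc. These comparisons use the same shControl libraries. In 20 simulations of unchanged groups a comparison had at most 1 gene called and no gene was shared, which sets no level for the overlap of longer lists. The covariance of the log2 fold changes was 0.0790, 0.0653 and 0.0851 in the 3 pairs, against 0.0561, 0.0544 and 0.0557 simulated, which leaves 0.0229, 0.0109 and 0.0295. The correlations across genes, which are not independent replicates, were 0.477, 0.377 and 0.537, against 0.485, 0.493 and 0.499 simulated. Without the 2 libraries that stand apart the covariances were 0.149, 0.142 and 0.141, against 0.0894, 0.0885 and 0.0905 simulated for those 13 libraries, and the correlations 0.585, 0.549 and 0.615, against 0.553, 0.545 and 0.632. The 3 shControl libraries give no 2 sets of at least 2 libraries, so part or all of the excess may come from the shared controls. In a test chosen after the data had been seen, 1 shControl library served 1 comparison and the other 2 the other, in 6 ways. The mean covariances were then -0.00125 (-0.0438 to 0.0252), -0.0141 (-0.0582 to 0.0108) and 0.0115 (-0.00430 to 0.0245), each below the value left with shared controls. The mean correlations were 0.00220, -0.0401 and 0.0401. Each range of covariances runs from a negative to a positive value, so no similarity over all genes is shown apart from the shared controls. The shared genes numbered 8, 9 and 14, and without shControl replicate 3 they were 3, 3 and 3.

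Whether added LINE-1 moved genes back was asked of the 27 genes called in shLINE_Orf1, Cryab, Rab3b and Hist1h1c among them. Of these, 20 (74.1%) had the opposite sign in shLINE_Orf1+LINE-1 against shLINE_Orf1. Both comparisons use the shLINE_Orf1 libraries. In simulations with all groups unchanged, shLINE_Orf1 and shControl included, the share among the 27 genes of smallest p was 92.6% (88.9% to 100%). Those simulated genes hold only shared chance values, while the 27 called here may hold real changes. The simulated share is therefore no reference for them, and the lower value does not tell whether LINE-1 moved genes back. Over all genes the covariance was -0.0976, more negative than in these simulations (-0.0583, with a range of -0.0659 to -0.0532). The simulations gave every library the same spread per gene, while the shared shLINE_Orf1 group holds replicate 1, which stands apart. Extra spread in the shared libraries alone makes this covariance more negative, so it does not tell whether LINE-1 moved genes back either. For the 13 libraries without the 2 that stand apart the covariance was -0.132, against -0.0881 simulated. Without shLINE_Orf1 replicate 3 the share was 100% of 12 genes, and without the 2 libraries that stand apart 71.9% of 139, against 94.6% simulated for those 13 libraries.

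The authors' deposited table gives a mixed model of an effect of young LINE-1. Of its 17921 genes, 477 had a p-value under 0.05, where chance gives 896, and each adjusted p was 1. Its headers do not give the direction of the group term. Across 14078 genes tested here, the term correlated most strongly, at -0.318, with the mean of shLINE_Orf1 and shLINE_Orf2 less the other 3 groups, while the other 9 pairings of groups gave -0.144 to 0.237. Read in that way, Col18a1, a basement membrane collagen, had an estimate of 1.60 ± 0.325 in the authors' deposited table (p = 0.000284 from the authors' mixed model, on a scale that is not named). Its log2 fold change here was -0.76 for the mean of shLINE_Orf1 and shLINE_Orf2 against shControl (adjusted p = 0.0938, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Axin2, a feedback gene of Wnt signalling, had an estimate of 1.51 ± 0.337 in the authors' deposited table (p = 0.000614, mixed model) and a log2 fold change of -0.32 here. Of the 45 genes called here for that mean, 44 were in the authors' deposited table, and with the sign read in that way 41 of these (93.2%) had the same direction, with the sign turned 3 (6.82%). Of the 477, 402 were tested here, 346 had the same direction against shControl with the sign read in that way and 56 with the sign turned, and 2 were called. The sign was read from the same data, so these shares are not independent of it. In shLINE_Orf1 and shLINE_Orf2 against the other 3 groups, a contrast chosen after the data had been seen, 3 genes were called, Cryab among them, and 3 had the direction of the authors' deposited table with the sign read from that contrast, 0 with the sign turned.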

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

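The 2 tests of explanations for the interferon genes were chosen only after the result was seen. Interferon and neuronal genes differed between shRNAs in a direct test, which is what brought these results here. In the mean of shLINE_Orf1 and shLINE_Orf2 against shLINE_MdV_I, 70 genes differed by edgeR's quasi-likelihood test. The median log2 fold change was 0.47 for the interferon response list and -0.23 for the neuronal differentiation list. In shLINE_Orf2 against shLINE_Orf1, the p53 target list differed with a median of -0.13, while its members such as Dcxr and Cdkn1a were not called singly. Of 100 splits of these 9 libraries into 3 groups of 3, 1 gave as many as 70 genes, the real one, and the highest other gave 57. The splits with 57 and 45 genes kept the 3 shLINE_MdV_I libraries together and so were close to the real one, and the 97 that parted them gave at most 1 gene. A random division of these libraries thus rarely gave such a count. Splits cannot exclude a difference in culture or preparation between groups, and the count was 11 without shLINE_MdV_I replicate 1. For its 13 lists 22 of the 100 splits gave as many, the highest other being 16, so chance is not excluded for the number of lists.

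Irf7, H2-D1 and the other interferon response genes were lower in shLINE_MdV_I than in shControl, and 2 explanations were tested here. Genes raised in shControl alone would leave shLINE_MdV_I level with the remaining groups, but its highest library had a list mean of -0.46 and the lowest of the other non-control libraries -0.20. Every group received a plasmid, so the values do not tell a fall in shLINE_MdV_I from a rise in all other groups. The last number of the library description is 12 in 2 shLINE_MdV_I libraries, and the list mean in the third, which ends in 1, was -0.53. A lower interferon response with this shRNA may be an effect of its LINE-1 target or of other RNAs that the shRNA matches. A culture or preparation shared by the libraries of this group could also give it, and no test here tells these apart.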

How the results depend on the processing

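The runs without the 2 libraries that stand apart, with 1 surrogate variable and with the added contrast were chosen only after the results were seen. Of 89 named gene results that were called, such as Cryab and Hist1h1c, 1683 alternative values gave 1248 with the same call, 435 with the call lost and 0 with the sign changed. Of 181 that were not called, 133 of 3356 values gained a call. Of 1038 values of 81 lists called, 814 kept the call, 200 lost it and 24 turned direction. The cause was not tested in any case below. Gene counts are in the order shLINE_Orf1, shLINE_Orf2, shLINE_MdV_I and shLINE_Orf1+LINE-1 against shControl, the mean of shLINE_Orf1 and shLINE_Orf2 against shControl and the same mean against shLINE_MdV_I, then shLINE_Orf1+LINE-1 and shLINE_Orf2, each against shLINE_Orf1. Without the 2 libraries that stand apart they were 139, 272, 389, 353, 292, 256, 0 and 24, with 1 surrogate variable 146, 276, 443, 317, 323, 185, 0 and 20, with DESeq2 214, 184, 305, 214, 196, 264, 20 and 125, and with limma-voom 613, 383, 383, 536, 432, 1032, 397 and 840. With only the compared groups in the fit they were 1, 4, 29, 4, 2, 15, 0 and 0. The description number as a covariate gave 44, 167, 39 and 511 for shLINE_Orf2, shLINE_MdV_I and shLINE_Orf1+LINE-1 against shControl and the mean against shLINE_MdV_I. Thinning gave 1 gene for shLINE_Orf1+LINE-1 against shLINE_Orf1, and no filter gave 11 for shLINE_Orf2 against shLINE_Orf1. With each library left out in turn, genes called ranged over 5 to 40, 3 to 13, 22 to 81, 2 to 22, 6 to 93, 11 to 96, 0 to 1 and 0 to 5, and lists over 5 to 10, 7 to 9, 8 to 11, 5 to 9, 5 to 11, 13 to 17, 7 to 14 and 9 to 13. With an estimated correlation, lists called were 0, 1, 1, 0, 0, 2, 0 and 1. Without the 2 libraries they were 4 for shLINE_Orf1 against shControl, 6 for shLINE_Orf1+LINE-1 against shLINE_Orf1 and 6 for the mean against shControl. Genes shared by shLINE_Orf1 and shLINE_Orf2, shLINE_Orf1 and shLINE_MdV_I, and shLINE_Orf2 and shLINE_MdV_I numbered 77, 71 and 111 without the 2 libraries, and 3 to 12, 3 to 12 and 2 to 7 with each library left out. The share of opposite signs with added LINE-1 ranged over 60% to 100%. The share with the direction of the deposited table ranged over 77.8% to 100%, with 80.9% by DESeq2 and 100% of 3 genes in the added contrast.

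Some lists turned direction, and their camera adjusted p is given here with "that library" for shLINE_Orf1 replicate 1. Against shControl, shLINE_Orf1 had immediate early genes turned without that library (0.290) and without the 2 (0.804), and ribosomal (0.125) and mitochondrially encoded genes (0.138) without that library. For shLINE_Orf1+LINE-1 against shLINE_Orf1, values without that library, without the 2 and with 1 surrogate variable were 0.940, 0.837 and 0.766 for immediate early genes, 0.653, 0.789 and 0.0464 for mitochondrially encoded genes and 0.155, 0.309 and 0.000242 for histone genes. With 1 surrogate variable oxidative phosphorylation (0.456) and ribosomal genes (0.000123) turned there too. For shLINE_Orf2 against shLINE_Orf1, ribosomal genes turned without that library (0.640), without the 2 (0.395) and with 1 surrogate variable (6.38e-07), and with 1 surrogate variable oxidative phosphorylation (0.585), mitochondrially encoded (0.814) and histone genes (0.585) turned as well. Ribosomal genes also turned in the mean against shControl, without shControl replicate 1 (0.107) or shLINE_Orf1 replicate 1 (0.240), and in the mean against shLINE_MdV_I with 1 surrogate variable (0.0198). With each library left out in turn, the adjusted p for shLINE_Orf1 against shControl ranged over 0.000308 to 0.290 for immediate early, 5.58e-21 to 0.224 for ribosomal and 3.99e-07 to 0.138 for mitochondrially encoded genes. For shLINE_Orf1+LINE-1 against shLINE_Orf1 it ranged over 0.000167 to 0.940 for immediate early, 2.34e-08 to 0.653 for mitochondrially encoded and 2.95e-05 to 0.155 for histone genes, and for ribosomal genes in the mean against shControl over 3.69e-15 to 0.240 and in shLINE_Orf2 against shLINE_Orf1 over 6.82e-22 to 0.640.

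The replicate numbers gave no clear sign of pairing the samples, and the labels do not say whether equal numbers share a culture or day. After group means were removed, the 30 pairs of libraries of equal number had a median correlation of -0.0221 (-0.271 to 0.180, 3 over 0.1), against 0.00671 for the 60 other pairs, and 4 of 15 libraries correlated best with 1 of their own number. A block by replicate number gave 4, 4, 55, 2, 10 and 33 genes for the comparisons in the order above up to the mean against shLINE_MdV_I.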

Other observations

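The tests of other cell types and of a difference in shControl alone were chosen only after the results were seen. Marker lists of cells outside the neural lineage were not called in any of the 8 comparisons: the lowest camera adjusted p was 0.152 for the 7 microglia and macrophage genes tested and 0.528 for the 12 endothelial, mural and fibroblast genes. The 20 heat shock genes reached 0.0513 and the 3 genes of the two-cell-like state 0.164. Cryab, a heat shock protein gene called higher in all 5 comparisons with shControl, rose without a call for heat shock genes as a list.

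Mitochondrial, ribosomal and histone genes place shLINE_Orf1 replicate 1 apart from the other libraries, and 3 explanations were tested. Its deviation per gene correlated with exonic length at -0.376, that of shControl replicate 2 at -0.472, and removing a length trend left 0.45 of 0.75 in oxidative phosphorylation genes and -0.83 of -0.77 in immediate early genes, so a length bias may be part of it and stays open. For a few genes taking most of the counts, the oxidative phosphorylation shift without the 50 genes of highest counts was 0.766, against 0.749 with them. Both values used TMM scaling, which already trims such genes. The shift could therefore hardly have changed, and no conclusion is drawn from it. As for RNA from cells of another type, 0 of 5 lists of other cell types were highest in that library. Types outside these lists were not covered, and the library's own shift also moved the lists (neuronal -0.58 relative to shControl). This explanation therefore stays open. No biological explanation was tested, since the library shares its group with 2 that do not stand apart.

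Cryab, Rab3b, Atp6v1b2 and Desi1 were higher and Hist1h1c and Mfge8 lower in all 4 groups than in shControl, which may come from shControl. The 1 shControl library that stands apart is not the whole cause, as 16 of 24 calls were kept without shControl replicate 2. Cryab and Hist1h1c differed among the 4 other groups (quasi-likelihood adjusted p = 4.92e-06 and 0.000942, Benjamini-Hochberg). This adjustment was made over only the genes called in all 4 groups, not over all genes tested. A difference of the shControl libraries alone would not give that. The part common to all 4 groups could still come from shControl, with log2 fold changes of at least 0.68 for Cryab and at most -0.95 for Hist1h1c. Rab3b, Atp6v1b2, Desi1 and Mfge8 were not called in the same test (0.162 to 0.989), and the genes were divided by this outcome. For these 4, a response to every shRNA and a difference of the shControl libraries alone cannot be told apart. A response to the LINE-1 shRNAs is the biological explanation the design gives, and the shared controls keep it open.

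Other splits of the libraries were compared for each count of genes called, Cryab and Irf7 among them. With 10 splits the design is too small for a share under 0.05. There the real counts were 27, 29, 90 and 21 genes for shLINE_Orf1, shLINE_Orf2, shLINE_MdV_I and shLINE_Orf1+LINE-1 against shControl, and the highest others 3232, 0, 0 and 0, with 2, 1, 1 and 1 splits giving as many. For shLINE_Orf1+LINE-1 and shLINE_Orf2 against shLINE_Orf1 the real count and the highest other were 0 by edgeR's quasi-likelihood test, with 1680 and 1729 genes at unadjusted p under 0.05, so 10 of 10 splits gave as many. The lists called in these 6 comparisons, in the same order, were 8, 7, 9, 10, 13 and 12, the highest others 11, 10, 13, 7, 13 and 13, and 7, 4, 2, 1, 3 and 2 splits gave as many. For the mean of shLINE_Orf1 and shLINE_Orf2 against shControl, 8 of 100 splits gave at least 45 genes (6 of the 97 that parted the shControl libraries), the highest other 3662, and 49 gave at least 9 lists, the highest other 14, so chance is not excluded for either. The splits with the highest counts put shControl replicate 2 and shLINE_Orf1 replicates 1 and 3 on 1 side, which points to a structure of the samples.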
